A study of Mus musculus with 4 samples.

How the data were processed

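RNA from sorted tumour cells (Tomato positive, P-cadherin positive) of 4 mice was sequenced after ribosomal RNA removal with a kit that keeps strand information, per the labels' protocols. The mice had 20 weeks of DMBA and were collected at 0 or 1 week after it was stopped, 2 mice per group, all different animals by their mouse identifiers. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.1, HTSeq, edgeR 3.2.3 and the mm9 build, without role or order. The annotation used for counting and the strand setting are not given in the sources used here. The reference in hand is of a later build, so no coordinates are printed.

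The authors deposited 1 table of 22222 gene symbols with a normalised signal per gene and library, called CPM. The columns sum to 1149287, 1011509, 867697 and 1092838 for on-DMBA replicates 1 and 2 and 1-week replicates 1 and 2, not to the same total as plain CPM would, so the deposited signal is CPM against a scaled library size and is named scaled CPM here. The design fixed before the data were examined had planned for plain CPM, and the planned log-scale test was kept. Within each library 100% of values were whole multiples of a single step at a tolerance of 0.01 reads. The step was 0.119, 0.180, 0.156 and 0.143 scaled CPM per read in the same order. Whole reads were recovered in this way and gave 9678682, 5635945, 5551937 and 7662159 reads. A floor of 3 reads corresponds to 0.356, 0.538, 0.469 and 0.428 scaled CPM and covers counting error only. Of the symbols, 20018 (90.1%) matched the gene table. The ribosomal RNA gene Rn45s took 6.17%, 4.77%, 3.94% and 3.35% of reads. Every column was mapped to a sample by its name in the sample descriptions.

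Genes at 1 scaled CPM or more in at least 2 libraries were tested (15419 genes), with R 4.3.3. The main test was limma 3.58.1 (lmFit, eBayes with a variance trend) on log2(scaled CPM + 0.5), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on this scale, 1 week minus on DMBA, and understate the change of low genes. An exact permutation test of 2 against 2 cannot give a two-sided p under 0.333. The 52 gene lists were fixed before the data were examined, and the 47 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Beside it were run camera with an estimated correlation, fry, and the percentile of each list's median among 10000 random lists matched on expression. Members that passed adjusted over the list alone were counted too, 21 over all lists. Replicate numbers mark different mice. The alternatives, whose effect is given in the closing part, were pseudocounts of 0.1 and 1, a filter of 5 scaled CPM and none, median ratio scaling, quantile normalization, eBayes without the trend and robust eBayes, a replicate block, leaving out each library in turn, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Where a library was left out, the lone library of its group was assumed to vary like the other group.

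The genes named were set by a rule written before the data were examined. It took the 8 genes with the largest change in each direction among genes past the threshold whose groups did not overlap, with a mean of at least 5 scaled CPM in the higher group and an ordinary symbol. Where fewer passed, the places went to the smallest unadjusted p, given as not passing, and that was the case for all 8 in both directions. It took from each called list, other than lists of other cell types, up to 3 passing members or else the 2 members with the smallest p. It took from each list of another cell type the most abundant measured member, and it took a fixed set of sort, keratinocyte, Wnt, retinoic acid, proliferation and DMBA response genes whatever their values. The rule gave 89 genes, of which some are not reported here.

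The tests were run on simulated counts drawn from the means and library sizes of the real libraries, with 50 genes changed at each of 4 folds. With a biological coefficient of variation of 0.7 for 4 libraries (15405 genes), limma recovered 0% of 2-fold, 2% of 4-fold, 10% of 8-fold and 50% of 32-fold changes with 0 false calls, edgeR recovered 50% of 32-fold changes with 0 false calls, and DESeq2 recovered 88% of them with 34 false calls. With a coefficient of variation of 0.337 (15586 genes), estimated without on-DMBA replicate 1, limma recovered 6%, 38%, 94% and 100% with 5 false calls. Both simulations fitted all 4 libraries, 2 against 2, with the same coefficient of variation for every gene. They therefore do not describe the fits of 1 library against 2.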

Results

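The data were 4 RNA-seq libraries of sorted mouse skin tumour cells. Keratoacanthomas, skin tumours that can regress without treatment, were raised by 20 weeks of DMBA, a carcinogenic polycyclic hydrocarbon. Tumours were collected either under DMBA (week 0, 2 mice) or 1 week after it was stopped (2 other mice). The RNA came from cells sorted as Tomato positive and P-cadherin positive, a gate for the labelled tumour epithelium. The libraries under DMBA held 9678682 and 5635945 recovered reads for replicates 1 and 2, and those at 1 week held 5551937 and 7662159. Levels are given as scaled CPM, the read count of a gene relative to a scaled library size, always in the order replicate 1, replicate 2. The title of the series names Wnt and retinoic acid signalling in tumour regression, so the comparison asks how the sorted tumour cells differed in these and other gene groups 1 week after DMBA was stopped.

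The 4 libraries did not carry epithelial transcripts to the same degree. Cdh3, which encodes the sort antigen P-cadherin, was at 325 and 3.23 on DMBA and 42.8 and 30.4 at 1 week. The basal keratin Krt14 was at 26654 and 202 on DMBA and 2644 and 1944 at 1 week, and its partner Krt5 was at 11731 and 55.3 on DMBA and 539 and 613 at 1 week. Krt10, a keratin of differentiating suprabasal cells, was at 2026 and 3.23 on DMBA and 3.59 and 5.42 at 1 week. The integrin Itga6 was at 976 and 206 on DMBA and 269.6 and 292 at 1 week, and the epithelial adhesion gene Epcam was at 125 and 1.44 on DMBA and 26.6 and 115 at 1 week. The 4 genes of other cells given next were lowest in on-DMBA replicate 1. The mesenchymal intermediate filament gene Vim was at 18.2 and 1083 on DMBA and 1750.4 and 1735 at 1 week, and the pan-leukocyte gene Ptprc was at 2.49 and 632 on DMBA and 393 and 850.2 at 1 week. Col3a1, a fibrillar collagen of fibroblasts, was at 68.5 and 20658 on DMBA and 20761 and 27662 at 1 week, and Lyz2, a lysozyme of myeloid cells, was at 1.19 and 8839 on DMBA and 3112 and 6663 at 1 week. On-DMBA replicate 1 thus held the highest level of each of the 6 epithelial genes and the lowest of each of these 4 genes of other cells.

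**Figure D1:**
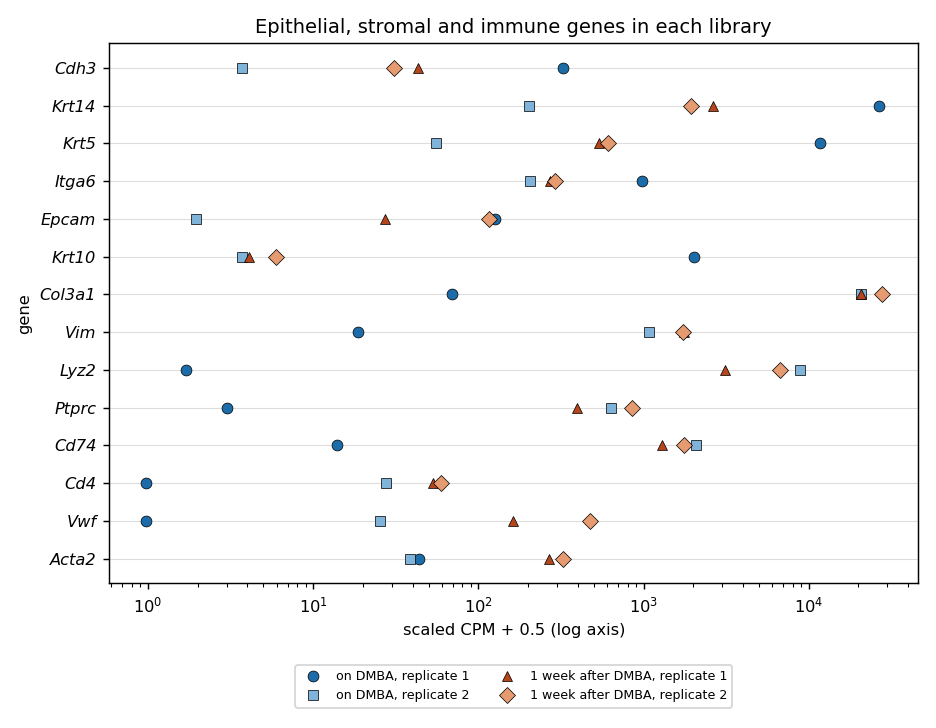
Levels of 14 epithelial, stromal and immune genes, as scaled CPM plus 0.5 on a log axis, with 1 point per library (2 on DMBA, 2 at 1 week after DMBA). On-DMBA replicate 1 lies at the high end for Krt14 (26654) and the low end for Col3a1 (68.5), and on-DMBA replicate 2 lies near the 1-week libraries for Col3a1 (20658) and below them for Krt14 (202).

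The difference between the replicates on DMBA was as large as that between the groups. Over the 15419 genes tested, the median absolute log2 difference was 1.02 between the on-DMBA libraries and 0.51 between the 1-week libraries. On-DMBA replicate 2 differed from the 1-week libraries by 0.49 and 0.42, and on-DMBA replicate 1 differed from them by 1.11 and 0.79. Between the on-DMBA libraries, 22.2% of genes differed by more than 4-fold, against 2.3% between the 1-week libraries.

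With all 4 libraries limma called no single gene, and the smallest p belonged to Mmp9, which encodes a gelatinase, followed by genes such as Crabp1 and Sfrp2. Of the 15419 genes, 0 were higher and 0 lower at 1 week in limma at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 352 higher and 30 lower genes, 382 in all, where chance gives 771. On recovered reads edgeR also called 0 and 0 genes (229 higher and 42 lower at an unadjusted p under 0.05), and DESeq2 called 16 higher and 3 lower. The groups did not overlap at 2161 genes higher and 1410 lower at 1 week, 23.2% of genes, where chance gives 33.3%. These counts rested on the on-DMBA libraries. Leaving out on-DMBA replicate 1, limma called 362 higher and 154 lower genes, and without on-DMBA replicate 2 it called 2212 and 1549. The counts stayed at 0 without either of the 1-week libraries. Of the genes named here, DESeq2 called Mmp9, Wisp2, Col13a1, Masp1, Crabp1, Podnl1, Sfrp2, Acta2, Itgax and Wnt10b higher and Gbp1, Krt10 and Rprl3 lower with all 4 libraries. Of these, Krt10 was high in on-DMBA replicate 1 alone. Elsewhere a gene is said to pass or not by limma.

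Among genes that did not pass in limma, the smallest unadjusted p values higher at 1 week belonged to Mmp9, Wisp2, Col13a1, Masp1, Crabp1, Podnl1, Sfrp2 and Acta2. The gelatinase gene Mmp9 was at 10.3 and 24.8 on DMBA and 576 and 612 at 1 week, a log2 difference of 5.17 (SE 0.60). Crabp1, a cytoplasmic binding protein for retinoic acid, was at 0.59 and 9.33 on DMBA and 515 and 282 at 1 week, a log2 difference of 6.86 (SE 1.13). Sfrp2, a secreted frizzled-related Wnt modulator, was at 0.83 and 4.67 on DMBA and 93.2 and 67.5 at 1 week, a log2 difference of 4.93 (SE 0.84). Wisp2, a secreted protein of the CCN family, was at 0.36 and 1.97 on DMBA and 38.8 and 86 at 1 week, and Masp1, a protease of the lectin complement pathway, was at 0.12 and 0.72 on DMBA and 33.9 and 17.4 at 1 week. The transmembrane collagen gene Col13a1 was at 3.44 and 4.31 on DMBA and 46.1 and 55.9 at 1 week, the proteoglycan gene Podnl1 at 0.59 and 1.62 on DMBA and 36.3 and 26.1 at 1 week and the smooth muscle actin gene Acta2 at 43.3 and 38 on DMBA and 267 and 324 at 1 week. Lower at 1 week, and also not passing, were Gbp1, Cldn1, Rprl3, Serpinb6c, Hddc3, Bmp2, Serpinb8 and Sertad4. Gbp1, an interferon-inducible GTPase, was at 21 and 49.2 on DMBA and 0.78 and 1 at 1 week, a log2 difference of -4.56 (SE 0.75). The tight junction gene Cldn1 was at 33.1 and 116 on DMBA and 5.16 and 6.85 at 1 week, a log2 difference of -3.28 (SE 0.78), and the ligand gene Bmp2 was at 17.3 and 21.7 on DMBA and 4.84 and 4.56 at 1 week, a log2 difference of -1.94 (SE 0.61). The serine protease inhibitor gene Serpinb8 was at 108 and 62.6 on DMBA and 19.1 and 29.9 at 1 week, and Serpinb6c was at 4.99 and 12.7 on DMBA and 0.31 and 1.14 at 1 week. Hddc3 was at 11.4 and 13.3 on DMBA and 2.34 and 2.42 at 1 week, and Sertad4 was at 37.3 and 16.1 on DMBA and 4.38 and 5.99 at 1 week. Rprl3, an RNA gene related to the RNase P RNA, was at 12 and 2.51 on DMBA and at 0 in both 1-week libraries. Its on-DMBA mean, carried mostly by replicate 1, was 16.2 times the mean 1-week floor of 3 reads per library. Gbp1, Serpinb6c and Rprl3 belong to families of similar genes, so reads may have been shared with a close copy.

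Camera on the limma values called neither Wnt list with all 4 libraries and the filter used here. The 20 measured Wnt/beta-catenin target genes had a median log2 difference of 0.38 (camera adjusted p = 0.16, 0.725 with an estimated correlation), with 5 members higher and 2 lower in both 1-week libraries than in both on-DMBA libraries and 0 past the threshold. Its median was 0.66 without on-DMBA replicate 1 and the list was called (adjusted p = 0.0014), and without on-DMBA replicate 2 it was -0.01. Without 1-week replicate 1 it was -0.33, and without 1-week replicate 2 it was 0.52 with a call (adjusted p = 0.0165). A filter of 5 scaled CPM also gave a call at 0.70. On recovered reads the median was 0.12 in edgeR and 0.07 in DESeq2, with no call. The 37 measured Wnt ligands, receptors and modulators had a median of -0.01 and a mean of 0.47, opposite in sign (camera adjusted p = 0.151, 0.725 with an estimated correlation). A filter of 5 scaled CPM gave a median of 0.06 with a call. Their median was 0.81 without on-DMBA replicate 1 and 0.30 without 1-week replicate 2, both with a call. Without on-DMBA replicate 2 the median was -0.24 and without 1-week replicate 1 it was -0.09, both with no call. It was -0.21 in edgeR and -0.26 in DESeq2, with no call. The ligand gene Wnt10b was at 11.3 and 2.33 on DMBA and 276 and 69.8 at 1 week, a log2 difference of 4.59 (SE 1.01). Wnt10a was at 101 and 4.85 on DMBA and 22.5 and 8.7 at 1 week and Wnt5a at 226 and 26.4 on DMBA and 163 and 123 at 1 week. Axin2, a feedback inhibitor induced by Wnt signalling, was at 13.1 and 5.74 on DMBA and 24.4 and 9.13 at 1 week, and the transcription factor gene Lef1 was at 0.95 and 1.44 on DMBA and 4.53 and 1.14 at 1 week. Ccnd1, which encodes cyclin D1, was at 671 and 229 on DMBA and 109 and 204 at 1 week, and Myc was at 53.8 and 4.31 on DMBA and 11.4 and 10.1 at 1 week. With all 4 libraries the difference passed in none of these 7 genes in limma or edgeR, and in Wnt10b alone in DESeq2 (log2 difference 4.75, adjusted p = 0.0276).

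The retinoic acid lists were not called either. The 27 measured genes of vitamin A transport, retinoic acid synthesis and breakdown had a median log2 difference of 0.07 (camera adjusted p = 0.468, 0.725 with an estimated correlation), with 4 members higher and 1 lower without overlap of the groups. In this list 0 genes passed over all genes tested and 1 gene, Crabp1, passed adjusted over the list alone. The 25 measured retinoid receptors and retinoic acid responsive genes had a median of 0.27 (adjusted p = 0.361, 0.725 with an estimated correlation), with 5 higher and 4 lower. The direction of both medians turned with the libraries kept. The first was -0.09 without 1-week replicate 2 and -0.03 without on-DMBA replicate 2. The second was -0.03 without on-DMBA replicate 2, -0.08 without 1-week replicate 1 and 0.80 without 1-week replicate 2, and it was -0.10 in edgeR and -0.15 in DESeq2. None of these gave a call. Cyp26b1, which breaks down retinoic acid, was at 32.1 and 22.6 on DMBA and 121 and 61.5 at 1 week, a log2 difference of 1.66 (SE 0.58). Among the enzymes that make retinoic acid, Aldh1a1 was at 0.47 and 11.5 on DMBA and 2.34 and 10.8 at 1 week, Aldh1a2 at 0.12 and 14.2 on DMBA and 8.75 and 7.7 at 1 week and Aldh1a3 at 7.6 and 148 on DMBA and 7.66 and 6.7 at 1 week. The retinol uptake receptor gene Stra6 was at 74.6 and 9.33 on DMBA and 74.4 and 71.5 at 1 week. The retinaldehyde reductase gene Dhrs3 was at 38.7 and 219.5 on DMBA and 71 and 87.3 at 1 week. Crabp2, a second cytoplasmic binding protein for retinoic acid, was at 158 and 3.95 on DMBA and 5.16 and 15.1 at 1 week. The receptor genes Rarb and Rarg were at 2.02 and 5.74 on DMBA and 1.88 and 3.14 at 1 week and at 121 and 26.9 on DMBA and 39.2 and 28 at 1 week. For Aldh1a3, Crabp2, Stra6 and Rarg the on-DMBA libraries differed from each other by more than the 1-week libraries did.

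**Figure D2:**
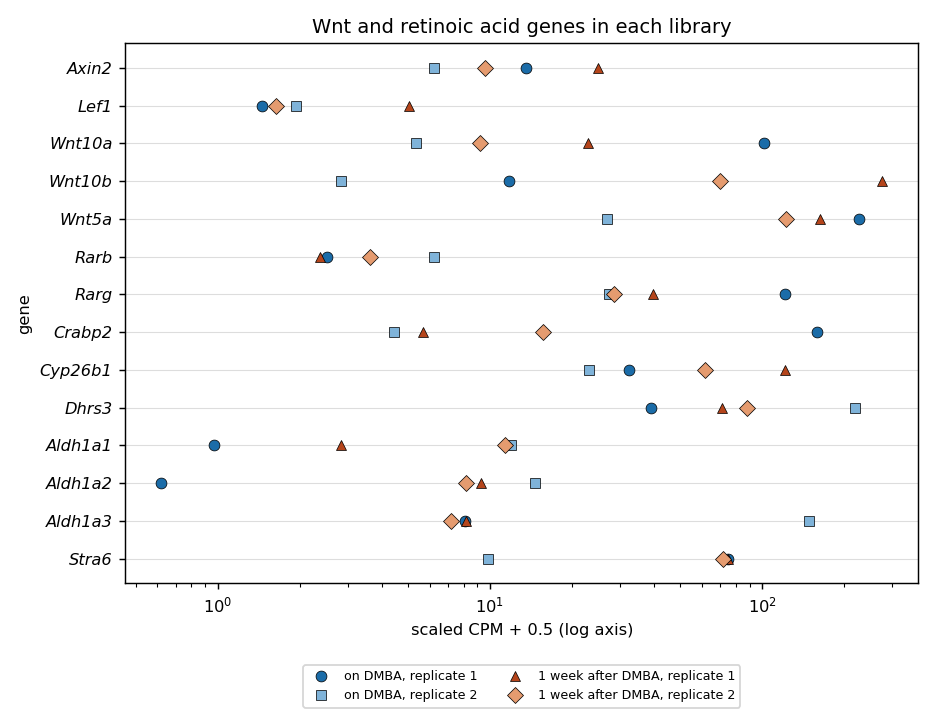
Levels of 14 Wnt and retinoic acid genes, as scaled CPM plus 0.5 on a log axis, with 1 point per library (2 on DMBA, 2 at 1 week after DMBA). Both 1-week libraries lie above both on-DMBA libraries for Wnt10b (276 and 69.8 against 11.3 and 2.33) and Cyp26b1 (121 and 61.5 against 32.1 and 22.6), while Aldh1a3 is high in on-DMBA replicate 2 alone (148).

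Lists of keratinocyte differentiation were called lower with the preset correlation, and their direction turned with the on-DMBA library that was kept. Spinous differentiation had a median log2 difference of -1.07 (camera adjusted p = 0.0222), granular and cornified layer -0.85 (adjusted p = 0.0266) and desmosome and epithelial junction -0.63 (adjusted p = 0.0223). Each had an adjusted p of 0.725 with an estimated correlation, and 0 of their members passed. These medians were, without on-DMBA replicate 1, 1.83, 0.64 and 2.39, and without on-DMBA replicate 2 they were -4.10, -2.65 and -3.53. Without 1-week replicate 2 the 3 medians were -0.76, -0.54 and -0.59, with no call, and without 1-week replicate 1 the granular list was at -1.39 with a call. On recovered reads the 3 lists were called at -3.07, -1.98 and -2.52 in edgeR and at -3.12, -2.01 and -2.56 in DESeq2. Cebpb, a transcription factor gene of the spinous list, was at 148 and 336 on DMBA and 442 and 371 at 1 week. The epidermal calmodulin-like gene Calm4 was at 422 and 3.23 on DMBA and 7.66 and 3.28 at 1 week, Il1f5 at 9.02 and 0.36 on DMBA and 1.41 and 0.14 at 1 week and the desmosomal plakophilin gene Pkp2 at 2.61 and 0.36 on DMBA and 5.63 and 3 at 1 week. Basal keratinocyte genes had a median of 0.04 (adjusted p = 0.852), which was 3.24 without on-DMBA replicate 1 and -2.08 without on-DMBA replicate 2, both with a call. On recovered reads its median was -1.03 in DESeq2, with a call. In log2 scaled CPM the median of the basal keratinocyte genes was 9.70, 4.22, 8.08 and 7.47 in on-DMBA replicates 1 and 2 and 1-week replicates 1 and 2.

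Proliferation and ribosome lists were also called lower with the preset correlation, and they turned as well. The median log2 difference was -0.71 for mitosis (camera adjusted p = 0.000123), -0.33 for DNA replication (adjusted p = 0.00628), -0.50 for cytosolic ribosomal proteins (adjusted p = 4e-05), -0.72 for ribosome biogenesis (adjusted p = 8.02e-05) and -0.23 for oxidative phosphorylation (adjusted p = 0.00863). Each of the 5 had an adjusted p of 0.725 with an estimated correlation, and 0 members passed. Without on-DMBA replicate 1 the medians were 0.68, 0.82, 0.26, 0.47 and 0.13 in the same order: mitosis, DNA replication and ribosome biogenesis were then called higher, and the other 2 calls were lost. Without on-DMBA replicate 2 they were -2.17, -1.67, -1.20, -1.98 and -0.68, all called lower. Without 1-week replicate 1 the median was 0.14 for oxidative phosphorylation and -0.13 for DNA replication, neither called, and -0.37 for mitosis, -0.19 for ribosomal proteins and -0.41 for ribosome biogenesis, all called. Without 1-week replicate 2 it was -0.65 for DNA replication, -0.76 for ribosomal proteins and -0.61 for oxidative phosphorylation, all called. On recovered reads edgeR and DESeq2 gave -1.23 and -1.27 for mitosis, -0.87 and -0.92 for DNA replication and -1.09 and -1.14 for ribosome biogenesis, all called, while oxidative phosphorylation (-0.27) was not called in DESeq2. The proliferation marker Mki67 was at 572 and 40.4 on DMBA and 53.3 and 88 at 1 week, Cenpf at 169 and 20.5 on DMBA and 13.1 and 29.5 at 1 week and Kif23 at 63.2 and 10.6 on DMBA and 7.5 and 10.7 at 1 week. Of the replication genes, Pola1 was at 159 and 52.4 on DMBA and 20 and 49.8 at 1 week. The nucleolar gene Ncl was at 835 and 103 on DMBA and 71.9 and 156 at 1 week, Gar1 at 24.8 and 3.23 on DMBA and 3.13 and 3.85 at 1 week, Rpl10 at 247 and 119 on DMBA and 79.2 and 126 at 1 week, Rps16 at 839 and 144 on DMBA and 110.3 and 151 at 1 week, Ndufa5 at 33.5 and 18.1 on DMBA and 11.2 and 18.4 at 1 week and Uqcrq at 26.7 and 9.15 on DMBA and 5.78 and 11.8 at 1 week. Rpl10 and Rps16 have processed pseudogenes with which reads can be shared.

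The p53 target genes and the cyclin dependent kinase inhibitors and pocket proteins were called lower in the same way. The p53 target genes had a median log2 difference of -0.54 (camera adjusted p = 0.000274, 0.668 with an estimated correlation), with 8 of 25 measured members lower and 1 higher without overlap of the groups. The cyclin dependent kinase inhibitors and pocket proteins had a median of -0.82 (adjusted p = 0.0406, 0.668 with an estimated correlation), with 3 of 9 lower and 1 higher. The medians were -0.10 and -0.11 without on-DMBA replicate 1, with no call. The p53 target list was called at -1.24 without on-DMBA replicate 2, at -0.77 in edgeR and at -0.82 in DESeq2. The kinase inhibitor list also lost its call without on-DMBA replicate 2 (-0.66) and without 1-week replicate 1 (-0.49). Cdkn2a was at 18.9 and 20.8 on DMBA and 4.38 and 6.28 at 1 week, a log2 difference of -1.82 (SE 0.62), and Cdkn2b was at 31.1 and 19.4 on DMBA and 11.2 and 11.7 at 1 week. Both encode inhibitors of the cyclin D dependent kinases. The p53 target Cdkn1a was at 49.5 and 12.6 on DMBA and 14.1 and 14 at 1 week and Eda2r at 23.5 and 13.8 on DMBA and 6.1 and 6.56 at 1 week. Gdf15 was at 0 and 7.18 on DMBA and 21.1 and 13.4 at 1 week. The DMBA-related genes did not pass in limma: Cyp1b1, which metabolises DMBA, was at 2.73 and 104 on DMBA and 33.3 and 45.6 at 1 week, and Cyp1a1 was at 0.12 and 0.36 on DMBA and 1.72 and 1 at 1 week, below the filter. Hras1, the oncogene often mutated by DMBA, was at 151 and 31.9 on DMBA and 49.7 and 56.2 at 1 week.

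Invasion, inflammatory and growth factor lists were called higher with the preset correlation. Whether tumour cells or other cells carried these lists was not tested. The invasion list had log2 medians of 4.38, 6.42, 7.43 and 7.81 in on-DMBA replicates 1 and 2 and 1-week replicates 1 and 2. Fibroblast markers had 2.46, 9.83, 10.37 and 10.26. The lysosome list had 6.1, 8.89, 8.23 and 8.41, and macrophage markers -0.04, 10.21, 8.91 and 9.72. The TGF-beta, BMP and YAP/TEAD medians were instead lowest in on-DMBA replicate 2. Mesenchymal transition and invasion had a median log2 difference of 2.23 (camera adjusted p = 3.71e-09), with 13 of 24 measured members higher and 0 lower without overlap, and 3 members, Mmp9, Mmp10 and Twist2, passing adjusted over the list alone. NF-kB and inflammatory cytokines had a median of 0.98 (adjusted p = 1.86e-06), with 15 of 30 higher and 1 lower. Both had an adjusted p of 0.602 with an estimated correlation. Mmp10, a stromelysin, was at 22.7 and 72.7 on DMBA and 1037 and 394 at 1 week, a log2 difference of 3.96 (SE 0.83). Il1rn, the interleukin 1 receptor antagonist, was at 19.7 and 16.1 on DMBA and 79.5 and 137 at 1 week, a log2 difference of 2.51 (SE 0.54), while the cytokine gene Tslp was at 22.9 and 2.33 on DMBA and 0.78 and 0.29 at 1 week. The TGF-beta pathway had a median of 0.49 (adjusted p = 0.0222), the BMP pathway 0.41 (adjusted p = 0.0463) and YAP/TEAD targets 0.63 (adjusted p = 0.00366), each with an adjusted p of 0.602 with an estimated correlation. Without on-DMBA replicate 2 these medians were 0.26, 0.29 and 0.18, with no call. Without 1-week replicate 2 the TGF-beta and BMP medians were 0.31 and 0.63, and without 1-week replicate 1 the BMP median was 0.42, all 3 with no call. Ltbp2 was at 19.6 and 18.5 on DMBA and 57.2 and 66.2 at 1 week and Inhba at 7.36 and 17.9 on DMBA and 49.5 and 31.5 at 1 week. Grem1, a secreted BMP antagonist, was at 0.95 and 19.7 on DMBA and 272 and 153 at 1 week, a log2 difference of 5.24 (SE 1.30). The YAP targets Cyr61 and Dlc1 were at 58 and 84.2 on DMBA and 260.1 and 363 at 1 week and at 16.7 and 32.7 on DMBA and 50.6 and 85 at 1 week. The immediate early and dissociation response list had a median of 0.48 (adjusted p = 0.0121) and lysosome genes 0.71 (adjusted p = 0.00628), both with an adjusted p of 0.725 with an estimated correlation. Nr4a1 was at 4.63 and 11.8 on DMBA and 34.2 and 35.9 at 1 week, Maff at 15.1 and 19 on DMBA and 33.6 and 41.5 at 1 week, Ctsa at 70.9 and 517 on DMBA and 448 and 509 at 1 week and Ctsz at 17.3 and 753 on DMBA and 639.7 and 996 at 1 week. Without on-DMBA replicate 1 the medians were 0.75 for invasion, 0.47 for inflammatory cytokines, 0.03 for immediate early genes with no call, and -0.25 for lysosome genes, which were then called lower. Without on-DMBA replicate 2 they were 3.68 for invasion, 1.25 for immediate early genes and 2.03 for lysosome genes, all called higher. The immediate early list was called at 0.31 in DESeq2. The lysosome median was 0.55 without 1-week replicate 2, 0.35 in edgeR and 0.31 in DESeq2, all with no call. On recovered reads the invasion list was called at 1.16 in edgeR and 1.11 in DESeq2. The BMP pathway was at 0.69 and 0.65 with no call, and the TGF-beta pathway (0.45) was not called in edgeR.

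Markers of other cell types differed between the libraries, but not all of their lists followed the groups. Macrophage medians were -0.04 in on-DMBA replicate 1 and 10.21 in replicate 2, against 8.91 and 9.72 at 1 week. In that list the groups did not overlap at 0 of 16 measured members. Of the 10 lists of other cell types that could be tested, 8 were called higher at 1 week with the preset correlation. Endothelial markers had a median log2 difference of 4.30 (camera adjusted p = 1.54e-15), with 12 of 12 members higher in both 1-week libraries than in both on-DMBA libraries and 10 passing adjusted over the list alone. Pericyte and smooth muscle markers had a median of 3.67 (adjusted p = 1.23e-11), with 8 of 8 higher without overlap and 6 passing adjusted over the list alone. Without on-DMBA replicate 1 these medians were 2.31 and 2.59. Vwf, a clotting factor of endothelial cells, was at 0.47 and 24.9 on DMBA and 161 and 477 at 1 week. Fibroblast markers had a median of 3.98 (adjusted p = 6.52e-08), macrophage and monocyte markers 4.06 (adjusted p = 3.51e-06) and dendritic and Langerhans cell markers 2.92 (adjusted p = 6.52e-08). Without on-DMBA replicate 1 the last 3 medians were 0.30, -0.91 and 0.05, with a call, lower, for macrophage markers only, and without on-DMBA replicate 2 they were 7.41, 9.11 and 5.78, all called higher. On recovered reads the fibroblast, dendritic and macrophage medians were 1.22, 1.03 and 0.13 in edgeR, all called, and 1.17, 0.98 and 0.08 in DESeq2, the last with no call. In the dendritic list 1 member, Itgax, passed adjusted over the list alone. T and NK cell markers had a median of 1.27 (adjusted p = 2.92e-06), melanocyte markers 1.59 (adjusted p = 0.00107) and skeletal muscle markers 1.64 (adjusted p = 0.000774). The melanocyte median was 2.76 without on-DMBA replicate 2, with a call. Calls were lost without on-DMBA replicate 1 for melanocyte (0.79) and skeletal muscle markers (1.40), and without on-DMBA replicate 2 for T and NK cell (2.01) and skeletal muscle markers (1.60). Schwann cell markers had a median of -0.80 and were called lower (adjusted p = 0.0291), but not without on-DMBA replicate 2 (0.32) or without 1-week replicate 1 (-0.35). It was -1.83 without on-DMBA replicate 1 and -1.36 without 1-week replicate 2, both called. Their median was -1.82 in edgeR and -1.87 in DESeq2, with a call. Neutrophil markers were called lower without on-DMBA replicate 1 (-0.58) and higher without on-DMBA replicate 2 (2.10); with all 4 libraries they had a median of 0.20 with no call (adjusted p = 0.196). With an estimated correlation none of these lists was called (adjusted p = 0.602 for endothelial, pericyte, T and NK cell, melanocyte, skeletal muscle and Schwann cell markers, 0.69 for fibroblast, 0.725 for macrophage and 0.666 for dendritic cell markers). The antigen presentation gene Cd74 was at 13.4 and 2079.6 on DMBA and 1295 and 1760.3 at 1 week, and the T cell gene Cd4 was at 0.47 and 27.3 on DMBA and 52.4 and 59.2 at 1 week. Il1r2 was at 3.32 and 16.3 on DMBA and 30 and 114 at 1 week, Mitf at 2.73 and 48.6 on DMBA and 24.7 and 37.1 at 1 week, Acta1 at 0.71 and 2.33 on DMBA and 5.78 and 5.28 at 1 week and Erbb3 at 132 and 33.9 on DMBA and 21.3 and 15.6 at 1 week. In lists with fewer than 5 measured members, Cd22 was at 0.59 and 27.8 on DMBA and 24.1 and 17.7 at 1 week, Hdc at 0 and 11.3 on DMBA and 14.4 and 18.8 at 1 week, Fabp4 at 678 and 37.3 on DMBA and 41.1 and 226 at 1 week and Alas2 at 3.21 and 10.4 on DMBA and 5 and 11.8 at 1 week.

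**Figure D3:**
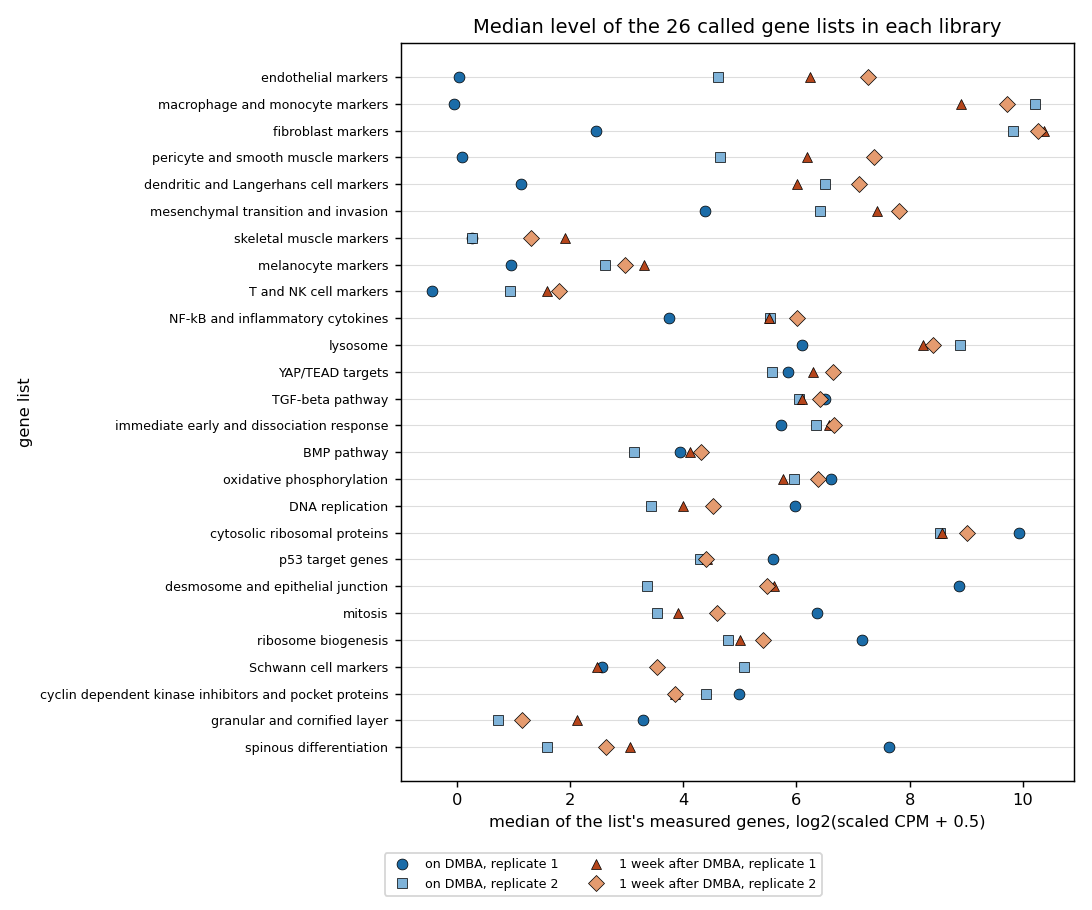
Median of each of the 26 called gene lists in each library, in log2 of scaled CPM plus 0.5, with 1 point per library (2 on DMBA, 2 at 1 week after DMBA), ordered by the median log2 difference. For macrophage and monocyte markers the medians are -0.04, 10.21, 8.91 and 9.72 in on-DMBA replicates 1 and 2 and 1-week replicates 1 and 2, and for endothelial markers 0.05, 4.61, 6.24 and 7.27.

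Of the 47 lists tested, 26 were called with the preset correlation, 15 higher and 11 lower. With an estimated correlation 0 were called, and fry called 0 (smallest adjusted p = 0.295). In the other lists camera made no call on the limma values of all 4 libraries. Their median log2 differences were -1.05 for stress keratins and alarmins, 0.15 for hair follicle stem cell genes, 0.05 for hair matrix, inner root sheath and hair shaft, and -0.22 for sebaceous gland. They were 0.14 for apoptosis regulators, -0.70 for aryl hydrocarbon receptor targets, -0.46 for NRF2 targets and -0.10 for ERK pathway output and EGF family ligands. They were 0.06 for interferon response, -0.25 for MHC class I presentation, 0.22 for the Notch pathway and -0.14 for the Hedgehog pathway. They were -0.24 for hypoxia and glycolysis, -0.40 for cholesterol synthesis and 0.26 for the unfolded protein and integrated stress response. On recovered reads stress keratins and alarmins were called lower in edgeR (-1.97, adjusted p = 0.0357) and DESeq2 (-2.02, adjusted p = 2.9e-05), and so were NRF2 targets (-0.54, adjusted p = 0.0193, and -0.58, adjusted p = 0.00111). DESeq2 also called aryl hydrocarbon receptor targets (-0.72, adjusted p = 0.00925), hypoxia and glycolysis (-0.61, adjusted p = 0.0166) and cholesterol synthesis (-0.82, adjusted p = 0.0425) lower. Calls also came with a library left out. Without on-DMBA replicate 1, stress keratins (1.2), NRF2 targets (0.25), the Notch pathway (0.32), hypoxia and glycolysis (0.93) and cholesterol synthesis (0.67) were called higher and interferon response (-0.87) and MHC class I presentation (-0.58) lower. Without on-DMBA replicate 2, stress keratins (-3.18), NRF2 targets (-1.21), hypoxia and glycolysis (-1.32) and cholesterol synthesis (-1.57) were called lower and interferon response (1.02) higher. Without 1-week replicate 1, apoptosis regulators (0.38) and the unfolded protein response (0.45) were called higher and the hair matrix list (-0.55) lower, and without 1-week replicate 2, NRF2 targets (-0.75), MHC class I presentation (-0.58) and cholesterol synthesis (-0.78) were called lower. Lists of B cell, mast cell, adipocyte and red blood cell markers had fewer than 5 measured members, and 0 mitochondrially encoded genes stood in the table.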

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

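The edgeR fits that also leave out a library were chosen after seeing the data; the other alternatives were fixed before. The counts of genes, 0 higher and 0 lower, were also 0 and 0 under both pseudocounts, both filters, both scalings, both eBayes settings and edgeR, with 229 to 484 higher and 23 to 72 lower genes at an unadjusted p under 0.05. Leaving out each library in turn gave 0 to 2212 higher and 0 to 1549 lower genes: 362 and 154 without on-DMBA replicate 1, 2212 and 1549 without on-DMBA replicate 2, and 0 and 0 without either 1-week library. With edgeR these were 462 and 389 without on-DMBA replicate 1, and 2458 and 1860 without on-DMBA replicate 2. With 1 library on DMBA the spread comes from the 1-week libraries alone, so these counts hold for that assumption. DESeq2 called 16 higher genes and 3 lower, among them Mmp9, Wisp2, Crabp1 and Wnt10b higher and Gbp1 and Krt10 lower. The Krt10 call rests on on-DMBA replicate 1 (2026), since replicate 2 (3.23) lay below both 1-week libraries (3.59 and 5.42). The cause was not tested. On simulated data DESeq2 made 34 false calls, but every gene and library there had the same spread. The real on-DMBA libraries differed from each other more than the 1-week libraries did, so this count cannot be carried over to the real calls.

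With the replicate block, 285 genes were higher and 3 lower. The numbers do not pair the mice: the correlation of same-numbered deviations across genes was 0.015, so the block has no design reason; the cause of its calls was not tested. The called lists numbered 26 and stayed within 1.5 times that under all settings but 2: 0 were called with an estimated correlation and 0 with fry, both of which allow for genes that vary together. Quantile normalization moved the median of all genes from -0.02 to -0.15.

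Calls of lists also moved. A pseudocount of 0.1 lost the calls of BMP pathway and Schwann cell markers. No filter lost the calls of TGF-beta pathway and BMP pathway; it gained stress keratins and alarmins, NRF2 targets and MHC class I presentation. A filter of 5 scaled CPM lost the calls of spinous differentiation, granular and cornified layer and cyclin dependent kinase inhibitors and pocket proteins; it gained Wnt/beta-catenin target genes and Wnt ligands, receptors and modulators. Quantile normalization lost the calls of spinous differentiation, desmosome and epithelial junction, DNA replication, cyclin dependent kinase inhibitors and pocket proteins and oxidative phosphorylation; it gained Notch pathway and unfolded protein and integrated stress response. The replicate block lost the calls of cyclin dependent kinase inhibitors and pocket proteins, immediate early and dissociation response, TGF-beta pathway, BMP pathway, YAP/TEAD targets and skeletal muscle markers; it gained stress keratins and alarmins and NRF2 targets. edgeR on recovered reads lost the calls of TGF-beta pathway, BMP pathway and lysosome; it gained stress keratins and alarmins and NRF2 targets. DESeq2 on recovered reads lost the calls of BMP pathway, oxidative phosphorylation, lysosome and macrophage and monocyte markers; it gained basal keratinocyte, stress keratins and alarmins, aryl hydrocarbon receptor targets, NRF2 targets, hypoxia and glycolysis and cholesterol synthesis. The cause was not tested. The filter of 5 scaled CPM also left too few members to test T and NK cell, skeletal muscle and Schwann cell markers, which had been called, and neutrophil markers, which had not. With no filter B cell, mast cell and adipocyte markers could be tested, and mast cell markers were called higher (0.90, adjusted p = 0.00481).

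Medians of lists and differences of genes that changed sign, and the call gained by Wnt/beta-catenin target genes, are given as log2 values, 1 week minus on DMBA; the cause was not tested. A filter of 5 scaled CPM gave 0.70 for Wnt/beta-catenin target genes, -0.07 for vitamin A transport, retinoic acid synthesis and breakdown, 0.06 for Wnt ligands, receptors and modulators, -0.04 for hair follicle stem cell and 0.00 for ERK pathway output and EGF family ligands, with 0.70 and 0.06 past the threshold. No filter gave 0.02 for Wnt ligands, receptors and modulators. A pseudocount of 0.1 gave -0.06 for vitamin A transport, retinoic acid synthesis and breakdown and -0.06 for hair matrix, inner root sheath and hair shaft, and a pseudocount of 1 gave 0.00 for basal keratinocyte and 0.00 for Cdh3. Quantile normalization gave -0.07 for vitamin A transport, retinoic acid synthesis and breakdown, -0.01 for retinoid receptors and retinoic acid responsive genes, 0.04 for Wnt ligands, receptors and modulators, -0.62 for hair matrix, inner root sheath and hair shaft, -0.10 for interferon response, -0.22 for neutrophil markers, -0.33 for Alas2, -0.17 for Aldh1a1 and 0.02 for Krt14. On recovered reads edgeR gave -0.10 for retinoid receptors and retinoic acid responsive genes, -0.99 for basal keratinocyte, -0.34 for hair matrix, inner root sheath and hair shaft, -0.14 for interferon response, -0.02 for Notch pathway, -2.05 for Cdh3 and -0.44 for Cyp1b1. DESeq2 gave -0.15 for retinoid receptors and retinoic acid responsive genes, -1.03 for basal keratinocyte, -0.36 for hair matrix, inner root sheath and hair shaft, -0.19 for interferon response, -0.07 for Notch pathway, -2.09 for Cdh3 and -0.49 for Cyp1b1.

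Leaving out each library in turn gave medians of -0.33 to 0.66 for Wnt/beta-catenin target genes, -0.09 to 0.22 for vitamin A transport, retinoic acid synthesis and breakdown and -0.08 to 0.80 for retinoid receptors and retinoic acid responsive genes. For the other lists, the range was -0.24 to 0.81 for Wnt ligands, receptors and modulators, -2.08 to 3.24 for basal keratinocyte, -4.10 to 1.83 for spinous differentiation, -2.65 to 0.64 for granular and cornified layer and -3.18 to 1.2 for stress keratins and alarmins. It ran from -3.53 to 2.39 for desmosome and epithelial junction, -0.01 to 0.43 for hair follicle stem cell, -0.99 to 0.38 for hair matrix, inner root sheath and hair shaft, -1.67 to 0.82 for DNA replication and -2.17 to 0.68 for mitosis. It ran from -0.10 to 0.38 for apoptosis regulators, -1.21 to 0.25 for NRF2 targets, -0.42 to 0.05 for ERK pathway output and EGF family ligands, -0.87 to 1.02 for interferon response and -0.58 to 0.07 for MHC class I presentation. It ran from -0.50 to 0.35 for Hedgehog pathway, -1.32 to 0.93 for hypoxia and glycolysis, -1.57 to 0.67 for cholesterol synthesis, -0.68 to 0.14 for oxidative phosphorylation and -1.20 to 0.26 for cytosolic ribosomal proteins. It ran from -1.98 to 0.47 for ribosome biogenesis, -0.09 to 0.45 for unfolded protein and integrated stress response, -0.25 to 2.03 for lysosome, -0.91 to 9.11 for macrophage and monocyte markers and -0.58 to 2.10 for neutrophil markers. It ran from -1.83 to 0.32 for Schwann cell markers. For aryl hydrocarbon receptor targets, which kept their sign and had no call in these fits, it ran from -0.96 to -0.23. The same range for genes was -0.41 to 1.15 for Alas2, -1.08 to 2.54 for Aldh1a1, -0.75 to 3.82 for Aldh1a2, -6.25 to 0.57 for Calm4 and -0.42 to 4.27 for Cd22. It was -0.46 to 6.76 for Cd74, -3.16 to 3.29 for Cdh3, -1.78 to 0.15 for Cdkn1a, -4.08 to 1.08 for Crabp2 and -0.12 to 2.74 for Ctsa. It was -1.41 to 3.61 for Cyp1b1, -1.47 to 1.01 for Dhrs3, -1.16 to 4.85 for Epcam, -2.81 to 1.36 for Fabp4 and -2.67 to 0.09 for Gar1. It was -1.51 to 0.72 for Hras1, -3.11 to 0.37 for Il1f5, -1.80 to 0.45 for Itga6, -8.68 to 0.40 for Krt10 and -3.56 to 3.48 for Krt14. It was -4.35 to 3.37 for Krt5, -0.03 to 1.59 for Lef1, -0.96 to 11.40 for Lyz2, -0.68 to 3.25 for Mitf and -3.05 to 0.76 for Mki67. It was -2.27 to 1.23 for Myc, -2.97 to 0.04 for Ncl, -0.13 to 7.59 for Ptprc, -1.09 to 0.22 for Rarb and -1.86 to 0.29 for Rarg. It was -0.03 to 2.90 for Stra6, -2.81 to 1.44 for Wnt10a and -0.67 to 2.40 for Wnt5a. Most of these ends come from leaving out 1 or the other on-DMBA library.

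Depth limits the low genes: 1 read is worth 0.119 to 0.180 scaled CPM, and Lef1, at 0.95 and 1.44 scaled CPM on DMBA, rests on few reads.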

Other observations

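The fit without on-DMBA replicate 1 compares both 1-week libraries with the on-DMBA library nearest to them, and its genes are named here after their values were seen. Among genes with a mean of at least 5 scaled CPM and an ordinary symbol, Wnt10b was the furthest above on-DMBA replicate 2. Its log2 difference was 5.62, followed by Crabp1 at 5.28 and Epcam at 4.85. SE values in this fit come from a spread pooled over genes, not from each gene's own replicates. Wnt10b was at 276 and 69.8 at 1 week with an SE of 0.55, and Mmp9 at 576 and 612 with an SE of 0.60. Apcdd1, a Wnt-induced inhibitor of Wnt signalling, was at 17.1, 3.59, 108 and 66.5 scaled CPM in on-DMBA replicates 1 and 2 and 1-week replicates 1 and 2, a difference of 4.38 (SE 0.55). Dkk2, a secreted Wnt modulator, was at 0.71, 6.46, 31.6 and 36.2 in the same order, a difference of 2.30 (SE 0.54). Itgax, the integrin of dendritic cells and some macrophages, was at 0.83, 10.4, 181 and 426, a difference of 4.67 (SE 0.57). The laminin chain gene Lamb3 was at 831, 12.4, 279.9 and 177, a difference of 4.11 (SE 0.57), and Epcam at 125, 1.44, 26.6 and 115, so that both were highest in on-DMBA replicate 1; without on-DMBA replicate 2 the differences were -1.90 for Lamb3, called lower, and -1.16 for Epcam with no call. In the same fit Aldh1a3 had a difference of -4.28, at 7.6, 148, 7.66 and 6.7 in the same order of libraries. Abca8a, Mgp and Scn7a were lower than in on-DMBA replicate 2 too. High levels in that library carried these differences. Against on-DMBA replicate 1, Aldh1a3 was close at 1 week and Abca8a, Mgp and Scn7a were higher. Abca8a was at 0.24, 697, 7.35 and 14.6 in the same order of libraries, Mgp at 0.47, 716, 12.3 and 20.2 and Scn7a at 0.36, 630.3, 21.1 and 56.6. Interferon response genes had a median of -0.87 in this fit and Schwann cell markers -1.83, both called lower with the preset correlation. In camera with an estimated correlation, run on all 4 libraries, the adjusted p was 0.993 for the interferon list and 0.602 for the Schwann list. Without on-DMBA replicate 2 the interferon list was called higher (1.02) and the Schwann list was at 0.32 with no call; with all 4 libraries they were at 0.06 and -0.80. Each value without an on-DMBA library rests on 1 library on DMBA.

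Krt10 per 100 of Krt14 was 7.60 and 1.60 in on-DMBA replicates 1 and 2 and 0.136 and 0.279 at 1 week, so that the ratio of this differentiation keratin to the basal keratin was lower in both 1-week libraries than in both on-DMBA libraries. Krt10 itself was at 2026 scaled CPM in on-DMBA replicate 1, 3.23 in replicate 2 and 3.59 and 5.42 at 1 week. Against on-DMBA replicate 2 the lower ratio thus came from higher Krt14, not from lower Krt10. Krt14 in on-DMBA replicate 2 was 0.759% of that in on-DMBA replicate 1, against 9.92% and 7.29% at 1 week. With 2 libraries per group an exact permutation test of the ratio cannot give a two-sided p under 0.333.

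The tests of explanations given here were chosen only after the results were seen. In 3 of the 4 libraries, genes of stromal and immune cells were high, and the epithelial genes named above were lower than in on-DMBA replicate 1. All 4 were nevertheless sorted on Tomato and P-cadherin, a gate that would remove stromal and immune cells. The 3 libraries were not alike in epithelial genes. The basal keratinocyte median was 9.70 and 4.22 in on-DMBA replicates 1 and 2 and 8.08 and 7.47 at 1 week, in log2 scaled CPM. Tumour cells that turned mesenchymal would alone leave blood cell genes low, but macrophage markers were high. They lay at least 8.78 log2 units above on-DMBA replicate 1 in each of these libraries. This argues against such tumour cells as the only source. It cannot tell whether some were present beside other cells. An exchange of labels between the groups has no partner. With 3 libraries alike in macrophage markers, each exchange leaves a macrophage difference of at least 8.94 within a group. This follows from the 4 values themselves and adds no evidence to them. Transcripts of macrophages, fibroblasts and endothelial cells were present in these 3 libraries, with list medians at least 4.22 log2 units above on-DMBA replicate 1. Lyz2 was at 1.19, 8839, 3112 and 6663 in on-DMBA replicates 1 and 2 and 1-week replicates 1 and 2. Col3a1 was at 68.5, 20658, 20761 and 27662 in the same order, and the sort antigen gene Cdh3 at 325, 3.23, 42.8 and 30.4. The 3 libraries thus did not hold transcripts of epithelium alone. How the other transcripts came there stays open, since these values restate the pattern and do not test its source. In on-DMBA replicate 1, 5 of 16 macrophage, 12 of 15 fibroblast and 4 of 12 endothelial markers reached 1 scaled CPM, and 0 of them stand in another of the lists. A single wrong label, or a library from cells sorted otherwise, stays open too.

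Of the 362 genes that limma called higher without on-DMBA replicate 1, 184 (50.8%) lay at least 2-fold above both on-DMBA libraries. This held in both 1-week libraries (all genes: 426 of 15419, 2.76%). The choice of genes above on-DMBA replicate 2 raises this share, so it cannot be compared with that of all genes. For the 184 genes themselves, a mixture of the 2 on-DMBA profiles as measured, in other proportions, would not give these levels. Spread between mice was not allowed for, and the 184 were picked by these same levels. The levels of a mixture lie between those of the 2 libraries. Of the 184, 165 reached 10 scaled CPM in both 1-week libraries. A mixture stays open for the other genes of the 362 and for the 154 called lower: 8 of these (5.2%) lay at least 2-fold below both on-DMBA libraries in both 1-week libraries, between the bounds of 5% and 10% set for this test. Of the 154, 140 (90.9%, all genes: 13.6%) were at least 4-fold lower in on-DMBA replicate 1 than in replicate 2, a share that the choice of genes raises too. More epithelium in the 1-week libraries than in on-DMBA replicate 2 may account for some of the 362, since the median basal keratinocyte marker lay at least 2.86 log2 units above that library in both. This value had been seen before its bound of 1 was set. A first test of this explanation, the share of these genes that were higher in on-DMBA replicate 1, was dropped because the choice of genes raised that share, and a test of the spread between the on-DMBA libraries as the reason for the absent limma calls was dropped because it repeated what was to be explained. More endothelial and mural cells may account for some of the 184: the smallest of the 4 median differences of endothelial and pericyte markers from on-DMBA replicate 2 was 1.77, and 15 of the 20 markers are among the 184, although the sort would remove such cells. The marker with the highest difference reached 3.45, while Wnt10b reached 5.62 and Crabp1 5.28. The time since DMBA was stopped stays open as a biological explanation and was not tested apart from these.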
